A study of Mus musculus with 2 samples.

How the data were processed

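Genomic DNA was taken from epidermis that the submitters had separated from dermis with 0.2% dispase, ligated to barcode adapters, immunoprecipitated with a 5-hmC antibody and sequenced on the Illumina platform, per the labels' protocols. The mice were 6 weeks old and received 3.125 mg of imiquimod daily as a 5% cream, or Vaseline, for 6 days. The mass of cream in the labels disagrees with this dose, so only the dose of the active compound is quoted. The groups were taken from the treatment label: 1 imiquimod library and 1 Vaseline library. The table names its columns WT-control and WT-treated. These were matched to the Vaseline and imiquimod samples by the words control and treated alone, on which every direction rests.

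Read processing with CASAVA, peak calling with MACS2 and the mm10 build are named in the submitters' processing notes, without versions. The aligner, the fragment extension, the treatment of duplicate reads, an input control and the scaling between libraries are not given in the sources used here. Per the file headers, the authors merged the enriched intervals of 4 libraries into numbered regions and annotated these with genes, promoters and CpG islands. The other 2 libraries, with 6 columns of values, are not samples of this series and were not used here, although the borders of the merged regions come from all 4. The highest region number was 166528, and numbers rose with position on all 20 chromosomes that held a region. The deposited table holds 364 regions, 0.219% of that number, which the authors had selected on a minimum of about 50 tags and 2-fold. These limits were read from the table's name and tested on its values. The smallest larger tag number was 49.5, and 362 regions differed by 2-fold or more before rounding.

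The deposited signal per library and region is an average tag pileup, a coverage value, and the highest pileup of any window. The averages were whole tag sums divided by the number of 32 bp windows in 95.1% of regions for Vaseline and 95.6% for imiquimod, within rounding at 3 decimals, against 17.9% and 15.7% with window numbers 5 too high. The authors' deposited tag score for a region equals the larger average times the region's length divided by 224 in all 364 regions, and their deposited log2 ratio equals the log2 of the ratio of the averages, without a pseudocount, in all 364 (tolerance 1e-06). Tag numbers of each library were therefore computed here as average times length divided by 224. Interval calls, promoter counts and CpG island counts were used as deposited by the authors. A second deposited sheet repeats the averages by region and gene: 441 of its 442 rows have the same gene and values as in the first sheet, the remaining row differs by a space, 3 rows are repeats, 2 pairs of region and gene have no row of that name and values, 1 of them through that space, and the sheet was not used further.

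Ratios of imiquimod over Vaseline were computed from the averages. Their intervals are Clopper-Pearson intervals of the share of tags in the imiquimod library, given the sum of both rounded tag numbers, at a confidence level of 95%. Sequenced fragments without molecular identifiers are not independent molecules, so the intervals cover counting error only. With 1 library per condition no test between conditions was made, leaving out a replicate was not possible, and genes were named by size. The rule, fixed before the data were examined, took the 12 regions with the greatest ratio in each direction that have an assigned gene, regions of genes on 12 fixed lists (356 genes), genes with 3 or more regions, and the 3 longest and the 3 highest regions of each library. Results for 2 genes that this rule names are not reported here.

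Coordinates are given as in the deposited table, in which the end minus the start equals the length, so starts may be counted from 0. Exon and intron overlap was taken from the GENCODE M21 basic annotation (GRCm38, the assembly that mm10 names), by any overlap with an exon of the assigned gene. Of 440 region and gene pairs, 416 had a gene of that symbol and chromosome in this annotation, and for 413 of these the deposited distance matched an annotated transcript start within 1000 bp. The authors' gene assignment reached at most 10364 bp upstream. A promoter was assigned to single-gene regions from 7692 bp upstream to 2787 bp downstream of the start. Counts of list members were compared with 10000 random lists drawn from 21911 protein-coding genes in 20 bins of gene length, as a description. Of 399 assigned symbols, 360 had a protein-coding gene there, 14 of them through a synonym.

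Alternatives fixed before the data were examined were a minimum of 100 tags, a minimum of 3-fold, equal sums of the average pileups over the listed regions, a pseudocount of 10, the highest pileup in place of the average, autosomes only, and regions inside genes only. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. On simulated tag numbers at the depth of the 364 regions, 97.8% of intervals held the simulated ratio. The simulated regions were not selected for large differences, so this share does not give the coverage for the selected regions. A permutation test of neighbouring directions called 5 of 100 simulations without structure at 0.05, and a stratified permutation test called 4 of 100 without and 100 of 100 with a planted difference among 270 simulated regions.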

Results

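5-Hydroxymethylcytosine (5-hmC), the oxidised form of 5-methylcytosine that TET enzymes make, was compared between imiquimod-treated and control mouse epidermis. Imiquimod is a Toll-like receptor 7 agonist whose repeated application to mouse skin gives a psoriasis-like dermatitis. The assay was hMeDIP-seq, in which sonicated DNA carrying 5-hmC is pulled down with an antibody and sequenced. The data held 1 library from the epidermis of C57BL/6J mice treated for 6 days with imiquimod cream and 1 library from mice treated with Vaseline, the vehicle control. How many mice contributed to each library is not given in the sources used here. No replicate spread exists, so every difference below compares these 2 libraries and carries no p-value between conditions. Intervals are exact 95% intervals for the ratio of the tag numbers, cover counting error only, and take no account of the regions having been selected for large differences.

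The values covered 364 genomic regions, with coordinates of the mm10 build. The regions were already selected: the higher library held at least 49.5 estimated tags in every region, and the smallest difference between the libraries was 1.9998-fold. Estimated tags summed over the regions to 19445 in the Vaseline library and 12942 in the imiquimod library. The median region held 53.8 tags in the Vaseline library and 28.9 in the imiquimod library. At these numbers the 95% interval of a log2 ratio extended a median of 0.71 to each side. The total depth of the libraries is unknown.

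The main comparison asked where 5-hmC was higher or lower in epidermis under imiquimod. Of the 364 regions, 271 (74.5%) had a lower 5-hmC tag pileup in the imiquimod library and 93 (25.5%) a higher one. The lower regions were assigned to 332 genes and the higher regions to 67, with 0 genes in common. Lower regions carried a median average pileup of 19.3 in Vaseline and 8.63 in imiquimod epidermis, and higher regions 10.2 and 22.4. The median difference was 2.18-fold for lower regions and 2.12-fold for higher regions. Most regions lay close to the selection limit, with 225 lower and 81 higher regions differing by less than 2.5-fold. Only 7 lower regions and 1 higher region reached 3-fold. The highest single-window pileup, from the same reads, went the same way as the average in all 271 lower and all 93 higher regions. The 95% interval of the ratio excluded a difference as small as 1.5-fold in 78 regions. The split depends on the scaling of the libraries, which is not given in the sources used here: with the imiquimod values raised by a factor of 1.15, a choice made after seeing the data, 85 regions stayed 2-fold lower beside the 93 higher ones, and with the average pileups summed over the listed regions made equal, a factor of 1.40, 11 did.

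**Figure D1:**
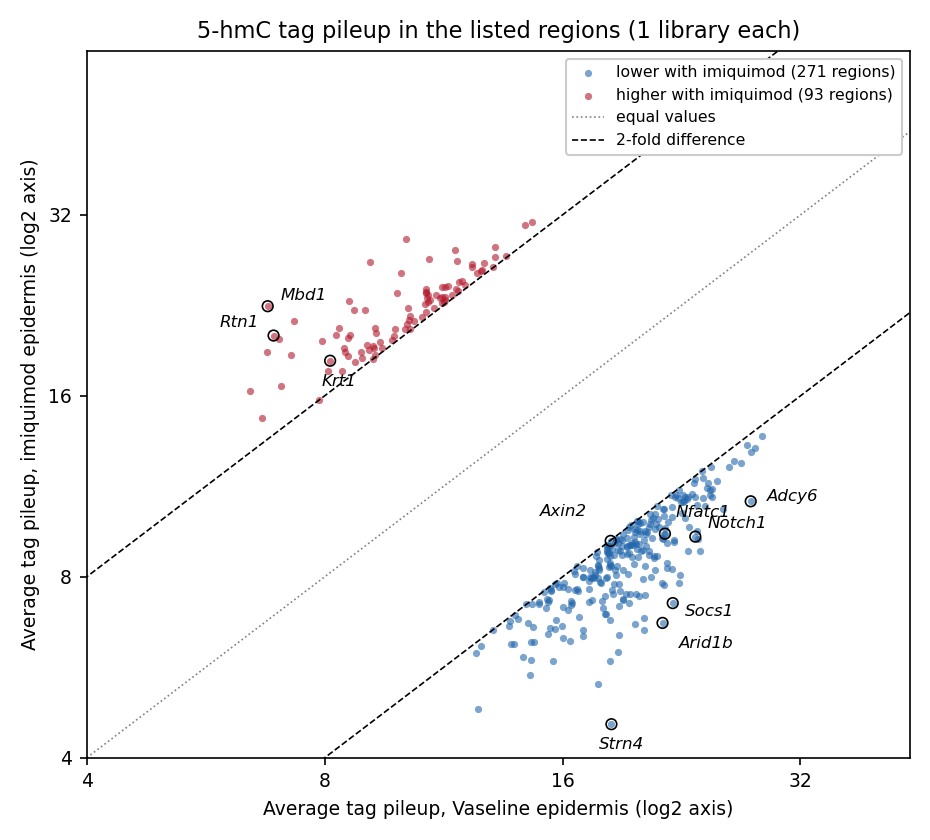
Average 5-hmC tag pileup of each listed region in the Vaseline library (horizontal, log2 axis) and the imiquimod library (vertical, log2 axis); each point is 1 region, dashed lines mark a 2-fold difference, and the dotted line marks equal values. The 271 lower and 93 higher regions crowd along the 2-fold lines. Strn4 lies farthest out among lower regions (4.05-fold lower) and Mbd1 among higher regions (3.33-fold higher). Adcy6 was labelled after its values were seen, as the region with the most tags.

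Interval calls followed the same split, but they come from the same reads as the averages that selected the regions, so they are not separate support. An enriched interval had been called in the Vaseline library in 269 of the 271 lower regions, and in the imiquimod library in 16 of them. All 93 higher regions held a called interval in the imiquimod library, and 24 held a called interval in the Vaseline library. Over all regions, 253 had an interval in the Vaseline library alone, 69 in the imiquimod library alone, 40 in both and 2 in neither.

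By average pileup, lower 5-hmC in imiquimod epidermis reached its greatest size at the 3' part of Strn4, which encodes a striatin scaffold of the STRIPAK phosphatase complex. This region (chromosome 7, 16839375 to 16840010, overlapping coding exon and 3210 bp upstream of the kinase gene Prkd2) had an average pileup of 18.45 in Vaseline and 4.55 in imiquimod epidermis, 4.05-fold lower (95% interval 2.15 to 8.01). By highest pileup its log2 ratio was -1.43, and other regions named below went lower, with -2.00 upstream of Col6a1. A region over coding exon of the bile acid synthesis gene Hsd3b7 (chromosome 7, 127802282 to 127803189) was 3.34-fold lower (2.08 to 5.87), from 71.9 to 21.5 tags. An intronic region of Arid1b, which encodes a subunit of the BAF chromatin remodelling complex, was 3.19-fold lower (1.81 to 5.85; chromosome 17, 5065409 to 5065976). A second intronic Arid1b region was 2.04-fold lower (1.30 to 3.38). Next came a region over coding exon of Rrad, a small GTPase gene (3.17-fold), a region 5844 bp upstream of 1700092K14Rik (3.13-fold) and an intron of Tbcel, a tubulin-binding gene (3.11-fold). A region 5187 bp upstream of Socs1, the inhibitor of cytokine signalling through JAK and STAT proteins, was 3.05-fold lower (1.74 to 5.64; chromosome 16, 10790459 to 10790987). That region overlaps the coding exon of the protamine gene Prm3 and lies near Tnp2, Prm2 and Prm1, so its assignment to Socs1 rests on distance alone. The remaining 5 of the 12 lower regions with the greatest difference and an assigned gene were 6038 bp upstream of the collagen gene Col6a1 (2.97-fold), in introns of Ispd (2.96-fold) and Clmn (2.95-fold), and over coding exons of Prom2, a prominin gene of epithelial membranes (2.87-fold), and of Wiz (2.79-fold).

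Higher 5-hmC in imiquimod epidermis was greatest within Mbd1, which encodes a methyl-CpG-binding protein. The region lies in an intron 528 bp from the start of the gene and holds a CpG island (chromosome 18, 74268520 to 74269113). Its average pileup was 6.78 in Vaseline and 22.6 in imiquimod epidermis, 3.33-fold higher (1.94 to 6.00). An intron of Rtn1, a reticulon gene, was 2.92-fold higher (1.73 to 5.44; chromosome 12, 72274270 to 72274871). The region 6442 bp upstream of Smox, the spermine oxidase gene, was 2.58-fold higher by its average pileup, but its highest single-window pileup differed by 0.50 on the log2 scale. Further higher regions lay in introns of Kpna4 (2.49-fold), Tshz2 (2.45-fold), the potassium channel genes Kcnh1 (2.40-fold) and Kcnmb4 (2.36-fold), 2310034O05Rik (2.39-fold), Acss3 (2.35-fold) and Ptpdc1 (2.33-fold), 7692 bp upstream of the serine protease gene Htra1 (2.47-fold) and 4301 bp upstream of Rbm12b1 (2.27-fold).

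Of the 51 genes on the list of Wnt, Notch, Hedgehog, TGF-beta and BMP pathway genes, 4 had a lower region, namely Notch1, Lrp5, Wnt7b and Axin2, and 0 a higher region. Coding sequence of Notch1, the receptor that promotes keratinocyte differentiation, was 2.52-fold lower (1.70 to 3.83), from 91.0 to 36.0 tags (chromosome 2, 26470595 to 26471460). Coding sequence of the Wnt co-receptor Lrp5 was 2.01-fold lower (1.25 to 3.27), a region of Wnt7b with a CpG island and coding exon 2.01-fold lower (1.27 to 3.21), and an intron of Axin2, a feedback inhibitor and target of Wnt signalling, 2.005-fold lower (1.26 to 3.24). Related genes off this list, named after their values were seen, went both ways: coding exon of the activin receptor gene Acvr2b was 2.04-fold lower and an intron of Bmp7 2.08-fold lower, while a region downstream of Rspo1, the gene of a Wnt agonist, was 2.13-fold higher and an intron of Ltbp1, the gene of a latent TGF-beta binding protein, had an average of 7.88 in Vaseline and 15.75 in imiquimod epidermis. Random gene lists matched on gene length held 0.822 genes with a lower region on average, and 0.95% of 10000 such lists held 4 or more. With regions inside the gene only, that share was 0.34%. Lists were drawn from all protein-coding genes, since the regions that could have been selected are not listed. For 12 lists and both directions 24 such shares were computed, and as many again with regions inside the gene only.

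Among hair follicle and epidermal stem cell genes, 2 of 31 had a lower region and 0 a higher region. An intron of Nfatc1, a regulator of hair follicle stem cell quiescence, was 2.28-fold lower (1.38 to 4.01; chromosome 18, 80614737 to 80615263). A region 5079 bp upstream of Tcf3 on chromosome 10 was 2.68-fold lower (1.59 to 4.76). This is the gene of the E-box protein E2A, not Tcf7l1, which older work on skin stem cells also calls TCF3. As many members or more were found in 8.20% of length-matched random lists. With regions inside the gene only, which leaves Nfatc1 and not Tcf3, 28.8% held 1 or more.

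Keratinocyte differentiation and barrier genes had 2 of 33 members with a higher region and 0 with a lower one, and both members came from the same region. It covers the start of Krt1, a keratin of suprabasal epidermis, and lies downstream of the neighbouring keratin gene Krt77 (chromosome 15, 101850138 to 101850872). The average pileup was 8.13 in Vaseline and 18.3 in imiquimod epidermis, 2.251-fold higher (1.39 to 3.64). Of the length-matched lists 0.14% held 2 or more genes with a higher region. That share counts 1 region as 2 genes, and the random lists were not matched on neighbouring genes, so it is not a like comparison. With regions inside the gene only, which leaves Krt1 alone, 3.38% held 1 or more. Related genes off this list, chosen after their values were seen and named further below, went both ways. Scel and Krt80 had lower regions and Lelp1 a higher one.

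The list of innate sensing, interferon, NF-kB and STAT genes contributed Socs1 alone among 36 members, and the list of 28 DNA methylation, hydroxymethylation and chromatin genes contributed Arid1b alone. No member had a listed region among the 42 IL-23, IL-17 and IL-36 axis genes, the 21 antimicrobial and alarmin genes, or the 29 basal and hyperproliferative keratinocyte genes. The same held for the markers of other cell types that epidermal sheets could contain, with 0 of 21 T cell genes, 0 of 24 myeloid, Langerhans and mast cell genes, 0 of 13 melanocyte and nerve genes and 0 of 28 fibroblast, endothelial, muscle and fat genes. Of the 42 IL-23, IL-17 and IL-36 axis genes 38, and of the 21 T cell genes 18, had a protein-coding gene of that symbol in the annotation used for the random lists. Length-matched random lists of the matched members held on average 0.183 to 0.471 genes with a lower region, so that a count of 0 says little about any of these lists. Tet1, Tet2 and Tet3 were not among the listed genes, which does not show that 5-hmC there was alike in both libraries.

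Several genes carried more than 1 lower region. Zbtb16, the gene of the zinc finger protein PLZF, held 7 of them, in introns and in 1 coding exon (chromosome 9, 48673265 to 48833998). Singly they were 2.01-fold to 2.59-fold lower, and they are 7 of 89 numbered regions in that span, of which the others are not listed. The coding exon region, 1680 bp long and 2787 bp from the start of Zbtb16, was the longest of all listed regions. Ptpn14, a phosphatase gene of the Hippo pathway, had 3 lower regions in introns (2.08-fold to 2.36-fold), out of 49 numbered regions in their span, and so did Sipa1l3 (2.19-fold to 2.54-fold), out of 62. Another 3 lower regions clustered within 3790 bp over the end of the proteasome gene Psmd3 and upstream of Csf3, the granulocyte colony-stimulating factor gene (2.07-fold to 2.34-fold). The gene 3110082I17Rik also had 3 (2.13-fold to 2.68-fold), some of which were shared with the neighbouring gene Gpr146.

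**Figure D2:**
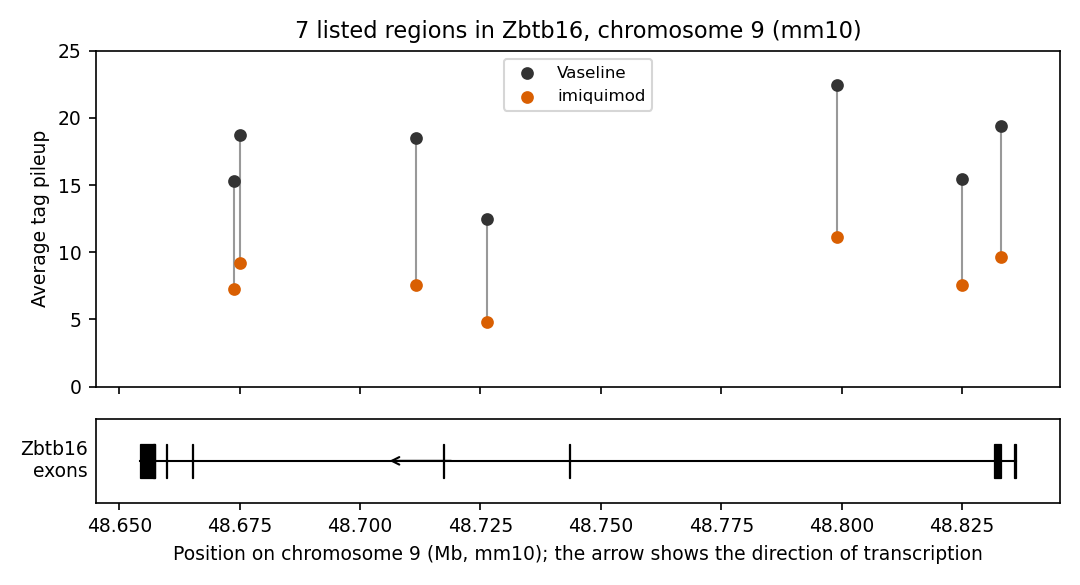
Average 5-hmC tag pileup (vertical) of the 7 listed regions in Zbtb16 by position on chromosome 9 in Mb (horizontal, mm10), with the Vaseline library in black, the imiquimod library in orange, and the exons of the gene below. All 7 regions lie between 2.01-fold and 2.59-fold lower in the imiquimod library.

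The longest and highest regions added few further genes. The third longest region, over coding exon of Gpr153 and near Hes3, a gene of the Notch-related HES family, was 2.003-fold lower. The highest Vaseline averages were 28.6 in a region with no assigned gene on chromosome 6 (2.09-fold lower) and 28.0 at coding exon of Cbs, the cystathionine beta-synthase gene (2.14-fold lower). The highest imiquimod averages were 31.1 at 4447 bp upstream of Tdpoz3 (2.12-fold higher), 30.8 in 1700095A21Rik (2.14-fold higher) and 29.1 in a region with no assigned gene on chromosome 9 (2.87-fold higher). Tdpoz3 belongs to a cluster of near-identical genes, so its tags could have come from other copies.

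The position of the regions differed between the directions. Inside a gene lay 225 of 271 lower regions (83.0%, exact 95% binomial interval 78.0 to 87.3) and 46 of 93 higher regions (49.5%, 38.9 to 60.03). An exon of the assigned gene was overlapped by 125 lower regions (46.1%, 40.1 to 52.3) and 5 higher regions (5.38%, 1.77 to 12.1). Introns alone held 94 lower regions (34.7%) and 38 higher regions (40.9%), with overlapping intervals. Regions inside genes whose symbol was absent from the annotation counted as neither exonic nor intronic, in either direction. Among them were the higher regions in Dnahc3, Diap1 and Ccdc11. The same holds for the exon shares within quartiles below. A CpG island was present in 27 lower regions (9.96%, 6.67 to 14.2) and 1 higher region (1.08%, 0.03 to 5.85), the Mbd1 region. A promoter was assigned to 68 lower regions (25.1%, 20.04 to 30.7) and 15 higher regions (16.1%, 9.32 to 25.2), with overlapping intervals. No gene was assigned to 28 lower regions (10.3%, 6.98 to 14.6) and 34 higher regions (36.6%, 26.8 to 47.2). Lower regions were also longer, with a median of 688 bp against 578 bp. These intervals treat regions as independent, although neighbouring regions are not.

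**Figure D3:**
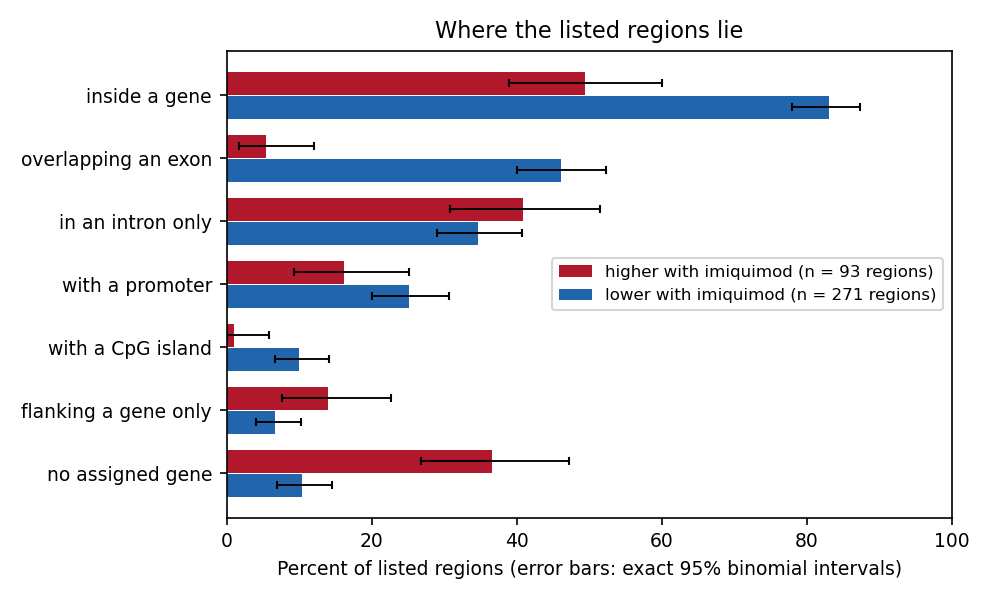
Percent of listed regions (horizontal) in each position class (vertical), for the 93 higher and 271 lower regions, with exact 95% binomial intervals as error bars. Exon overlap (46.1% against 5.38%) and location inside a gene (83.0% against 49.5%) differ most in favour of lower regions, and regions without an assigned gene (10.3% against 36.6%) in favour of higher regions.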

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

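All 364 regions kept their sign with the highest pileup in place of the average, though both come from the same reads. Equal sums and the pseudocount cannot turn the sign of a region listed at 2-fold, so they say nothing about its stability. Among 180 log2 values of 60 named regions under these 3 alternatives, 7 shifted by more than their interval extends to each side on average. This is not a count of values outside their intervals. A minimum of 100 tags left 10 lower and 0 higher regions, and 3-fold left 7 and 1. Equal sums of the average pileups over the listed regions, a factor of 1.40 on imiquimod, left 11 regions 2-fold lower beside the 93 higher ones, and a factor of 1.15, chosen after seeing the data, left 85. Regions that such a scaling would add to the higher side are not listed, so these counts do not replace the reported split. A pseudocount of 10 left 0 lower and 0 higher regions at 2-fold, since it shrinks every ratio at these averages. The highest pileup left 201 lower and 61 higher regions at 2-fold. Autosomes alone left 271 and 91. Members of the fixed lists with a lower region numbered 8, with 6 for regions inside the gene, 2 at 3-fold and 0 at 100 tags. Members with a higher region numbered 2, with 1, 0 and 0. The median log2 ratios, 1.09 and -1.13, were 1.73 and -1.67 at 3-fold, where a higher minimum raises them by construction. No higher region held 100 tags, and the highest estimated tag number in the imiquimod library was 81.6.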

Other observations

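The tests of exon overlap within quartiles below were set out before their results were seen, and the tests of neighbouring directions, placement in Zbtb16 and gene number near regions without a gene were chosen afterwards; equal sums were set out before and read against a scaling difference only afterwards. Beyond the fixed lists, 2 gene groups stood out when the assigned genes were read through, so both were chosen after their values were seen. Genes of hemidesmosomes, desmosomes and plakins, which anchor keratinocytes to the basement membrane and to each other, had 5 of 25 members with a lower region and 0 with a higher one. Coding exon of Dst, the gene of the hemidesmosome plakin BPAG1, was 2.61-fold lower in imiquimod epidermis (95% interval 1.56 to 4.68), an intron of Plec, the plectin gene, 2.42-fold (1.51 to 3.99), a region upstream of the tetraspanin gene Cd151 2.38-fold (1.43 to 3.87), and coding exon of Lama5, a laminin chain gene, 2.02-fold (1.27 to 3.32). Eppk1, the epiplakin gene, had 2 lower regions, 2.41-fold and 2.2500-fold. Length-matched random lists held 0.363 such genes on average and at most 4, over 10000 draws. The 5 members include the laminin gene Lama5, and the count that remains without it equals this random maximum. Genes of the circadian clock had 3 of 21 members with a lower region, namely Npas2 (2.19-fold), Nr1d1 (2.13-fold, in sequence shared with the overlapping gene Thra) and Per1 (2.02-fold), and 30 of 10000 random lists held as many. Both shares overstate the evidence, because the groups were chosen from the list itself.

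Other epidermal genes with single lower regions, also chosen after their values were seen, were Il4ra, the interleukin 4 receptor alpha gene (2.32-fold, 1.42 to 4.01), the retinoic acid receptor gene Rara (2.21-fold, 1.58 to 3.17), the planar cell polarity gene Vangl2 (2.21-fold, 1.44 to 3.48), the cornified envelope gene Scel (2.21-fold, 1.34 to 3.74) and the keratin gene Krt80 (2.13-fold, 1.29 to 3.56). Higher regions lay in an intron of Lelp1, a gene next to the late cornified envelope cluster (2.18-fold, 1.41 to 3.33), and near Aqp3, the aquaporin of basal keratinocytes (2.17-fold, 1.35 to 3.68).

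The first pattern was that more regions were lower than higher. Counting noise may have placed many single regions in the table: at the median of 82 tags per region in both libraries together, chance gives a 2-fold excess in a given direction in 0.132% of regions, or 220.02 regions per direction if all 166528 numbered regions had that depth, which is not known. For lower regions counting noise with equally scaled libraries leaves the list unaccounted for, but counting noise combined with a scaling difference was not tested. Of 74 neighbouring pairs of listed regions (within 50 region numbers and at least 309 bp apart), 61 were both lower. Over 100000 permutations of the directions the mean was 41.0 and the maximum 58 (one-sided permutation p = 1e-05, the smallest they can give). Pairs sharing a direction, both lower or both higher, numbered 67 of 74 against a permutation maximum of 63. Without Zbtb16 these were 61 of 68 against a maximum of 57. Pairs both lower are not given separately without Zbtb16. The permutation covers both directions together, so higher regions lying apart from other listed regions could leave the same excess. In 8 lower regions the tags were split between the libraries too unevenly for chance (one-sided binomial tail times 166528 under 0.05). Of the lower regions 17.0% (12.7 to 22.0) reached 2.5-fold where counting noise at the same tag sums gives 8.72%. These comparisons of tag split and size take the libraries as equally scaled. For higher regions counting noise stays open, with 6 pairs both higher against a mean of 4.78 (one-sided permutation p = 0.343). A split that uneven was found in 0 higher regions, and 12.9% (6.85 to 21.5) reached 2.5-fold or more where counting noise gives 8.27%. A uniform scaling difference between the 2 libraries stays open, because their scaling is not given and unselected regions are not listed; making the sums over the listed regions equal left 11 lower regions at 2-fold, but these sums carry the selected imbalance itself, so this count decides nothing.

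A second pattern was that lower regions lay in gene-dense and exonic sequence, with only 5 in-gene higher regions over an exon. The median number of protein-coding genes within 500 kb was 19 for lower and 8 for higher regions. Among regions with no assigned gene the medians were 12.5 and 5.5, a difference of 7 (two-sided permutation p = 0.00504), so a different yield of gene-dense, and thus often GC-rich, sequence in the 2 libraries may contribute and cannot be told apart from an effect of imiquimod with 1 library each. Gene number of the neighbourhood alone leaves the exon overlap unaccounted for: within quartiles of gene number, the share of in-gene regions over an exon was 37.0 percentage points greater for lower than for higher regions (two-sided permutation p = 0.0001). Quartiles 3 and 4, with the most genes, held only 4 higher in-gene regions each, so the comparison there is thin. Of these, 0 and 2 lay over an exon, against 36 of 61 and 51 of 64 lower regions. The greater length of lower regions leaves the exon overlap unaccounted for too, with a difference of 47.4 points within quartiles of length. The permutation test gave two-sided p = 1e-05, the smallest it can give, with regions permuted as if independent. The GC content of the regions was not computed, and the length of the host genes was not taken into account. Neither quartile comparison therefore excludes a different yield of GC-rich sequence within genes.

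The last pattern was in Zbtb16, which held 7 lower regions among 89 consecutive numbered regions, where 0.145 would be expected if lower regions were spread evenly, and 0 higher regions. Uniform placement of lower regions among the numbered regions never reached this, with 0 of 10000 draws holding 7 in any span of 89 and a maximum of 6. The draws treat all numbered regions as alike, and a local excess of deep regions in Zbtb16, which would offer more regions to the selection, was not tested. An effect of imiquimod on this gene is untested with 1 library per condition.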
